A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

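The series holds 6 polyA RNA-seq libraries of Schizosaccharomyces pombe, 3 wild-type and 3 seb1-G476S. Per the labels' protocols, RNA was purified with hot acid phenol, libraries were made with the Illumina TruSeq stranded mRNA kit and sequenced paired-end on a NovaSeq instrument. Per the series' design text, the wild-type libraries were sequenced within the same run and had been deposited earlier, and each group has biological replicates. Groups and replicate numbers were taken from the sample titles and strain descriptions.

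The authors deposited a table of raw counts per annotated feature for the 6 libraries, per the file headers, and the columns held whole numbers with no scaling. The submitters' processing notes name HISAT2 2.1.0, SAMtools, HTSeq 0.10.0, DESeq2 and the genome build ASM294v2. The annotation release and the strand option of the counting were not given in the sources used here. A second deposited table holds the authors' own comparison: log2 fold changes with their standard errors, the test statistic as a score, p-values and adjusted p-values, per the file headers. It also gives the authors' group averages, a signal made of counts divided by size factors, and a mean over libraries. That mean lay over 2-fold from the mean of the 2 group averages for 87 of 5118 features. The authors' fit may therefore have held further libraries, and none beyond the 6 was used here. Counts on the wrong or either strand were checked for. Of 356 coding genes lying wholly under an opposite-strand feature of the table, 329 were tested, and their median wild-type level was 31.8 CPM, against 54.6 CPM for all tested coding genes. Counting without strand would by default leave such reads unassigned.

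The count table had 6987 rows. One identifier stood on 2 rows, 1 of them all zero, and these were summed, which left 6986 features. Gene names and product descriptions were taken from the authors' deposited comparison, and the antisense, intergenic and possible alternative UTR classes rest on them. Feature type, neighbours, chromosome and gene length were taken from the RefSeq annotation of assembly ASM294v3. Features were matched by identifier: 6833 matched directly, 13 through a synonym and 140 did not. The assembly differs from the one the authors used, so none of its coordinates is given. Every tested coding gene had a length.

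The main test was edgeR 4.0.16 (R 4.3.3), the quasi-likelihood test of mutant against wild type with TMM scaling, two-sided, on features kept by filterByExpr with a minimum count of 10. Benjamini-Hochberg adjustment ran over the 6046 features kept, and a call means an adjusted p under 0.05. The fit had 4 residual degrees of freedom, and standard errors are the log2 fold change over the square root of the F statistic. CPM values use TMM library sizes. The 23 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the lists. Each list's members were also adjusted over the list alone. The correlation was estimated per list as an alternative, and all 10 lists called with the preset value lost the call. In fry, a p tests whether the genes of a list move one way on balance. Upstream neighbours were compared with camera among coding genes, and gene length with Spearman's rho.

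The genes named follow a rule set before the data were examined. They are pho1, pho84, tgp1, seb1 and rpb1 with non-coding features directly upstream of the phosphate genes; the 12 largest rises and 12 largest falls among called features with at least 5 CPM in the higher group and no overlap between groups; up to 4 called members of each list by size of change; and ura4, leu1, ade6 and the M cell markers as a check of strain background. Genes of the closing observations outside this rule were chosen after their values were seen.

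Depth was 21013941 to 27910803 counts per library, and 1 count corresponds to between 0.0371 and 0.0445 CPM. A count of 0 allows up to 3 counts, which covers counting error only. No 2 libraries agreed within sampling noise: the lowest chi-square per degree of freedom of a pair was 3.87. The correlation of log2 CPM was 0.9909 to 0.9962 between wild-type libraries, 0.9959 to 0.9976 between mutant libraries and 0.9645 to 0.9744 between groups. Wild-type replicate 3 was the library farthest from the others of its group.

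The procedure was tested on simulated data with the real libraries' sizes and means, for this comparison, over 6023 features. It recovered 70.1% of 67 features changed 1.5-fold, 98.5% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, with 5.82% false among all calls. In the data 55% of tested features were called, a far larger share than was changed in the simulation. The recovery and the false share therefore need not carry over to the data. A planted list of raised genes was recovered and 0 of 20 unchanged lists were called. Counts were drawn independently for each gene, so this does not bear on list calls where genes vary together.

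The alternatives were median-of-ratios size factors, library totals alone, no low-count filter, a stricter filter of 50 counts in 3 libraries, the replicate number as a block, leaving out each library in turn, the DESeq2 1.42.0 Wald test, limma-voom, edgeR's test against a 1.5-fold change, an estimated correlation, fry, and non-coding identifiers left out. Others were added after seeing the data: coding genes tested alone, lists against coding genes, the ribosomal list without antisense features and counted upstream neighbours only. Intervals in the closing section are 95% bootstrap intervals over features, which do not measure the spread between libraries. Permutation tests there used 100000 permutations. Both were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.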

Results

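Polyadenylated RNA was sequenced from vegetatively growing fission yeast, Schizosaccharomyces pombe, kept in log phase in YES, a rich medium, at 30 °C. The data comprised 3 wild-type libraries and 3 libraries of a strain with the seb1-G476S mutation, described in the series' design text as biological replicates. Seb1 is an essential RNA-binding protein that acts in transcription termination and 3'-end processing by RNA polymerase II. Both strains were h+ and carried a drug marker at the rpb1 locus, NatMX in the wild type and KanMX in the mutant, so the marker differed together with the seb1 allele. The counts assigned to annotated features summed to 23150580, 24496579 and 21013941 in wild-type replicates 1, 2 and 3, and to 24767798, 27910803 and 23705340 in mutant replicates 1, 2 and 3. Between 6369 and 6462 features had a count in each library. The most abundant feature, fba1, held 0.834% of all counts. Levels below are CPM, counts relative to the scaled library total, as mean ± SD over the 3 libraries of a group, and fold changes are log2 values of the mutant over the wild type with their standard errors (SE).

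The comparison of the mutant with the wild type addressed how an allele of a termination factor, obtained in a search for suppressors of interference by long non-coding RNA (lncRNA) transcription, alters the transcriptome. The genes for phosphate acquisition rose in the mutant. The glycerophosphodiester transporter gene tgp1 (SPBC1271.09, chromosome II) rose 9.23-fold, from 11.2 ± 0.879 to 104 ± 8.03 CPM. The secreted acid phosphatase gene pho1 (SPBP4G3.02, chromosome II) rose 3.79-fold, from 1267 ± 63.9 to 4803 ± 389 CPM, and the phosphate transporter gene pho84 (SPBC8E4.01c, chromosome II) rose 1.40-fold, from 1580 ± 12.6 to 2214 ± 131 CPM. The mRNA of seb1 itself (SPAC222.09, chromosome I) rose 2.97-fold, from 120 ± 12.3 to 357 ± 14.1 CPM.

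In edgeR's quasi-likelihood test the log2 fold change was 3.21 for tgp1 (SE 0.0921, adjusted p = 3.24e-08), 1.92 for pho1 (SE 0.0755, adjusted p = 2.18e-07), 0.49 for pho84 (SE 0.0596, adjusted p = 0.000186) and 1.57 for seb1 (SE 0.0769, adjusted p = 7.33e-07). In each of these 4 genes all 3 mutant libraries lay above all 3 wild-type libraries. The gene for the largest RNA polymerase II subunit, rpb1 (SPBC28F2.12), was at 152 ± 12.8 CPM in the wild type and 151 ± 6.62 CPM in the mutant, with a log2 fold change of -0.0035 (SE 0.0709, adjusted p = 0.971). A count per gene holds no base of the transcript, so these levels do not check which libraries carry the mutation.

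**Figure D1:**
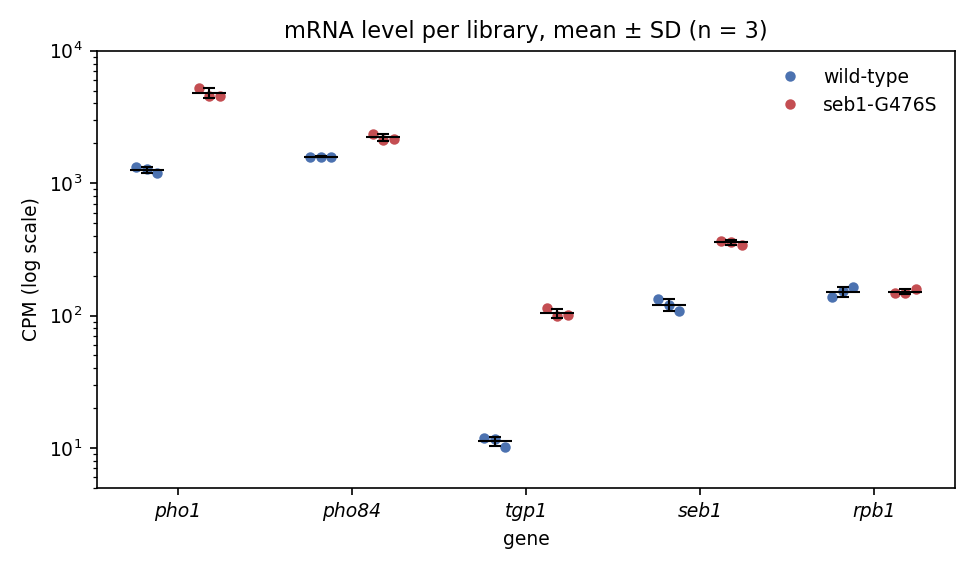
CPM on a log axis of pho1, pho84, tgp1, seb1 and rpb1 in each of the 3 wild-type libraries (blue) and the 3 seb1-G476S libraries (red), with black bars at the mean ± SD. The mutant libraries lie above the wild-type libraries for pho1, pho84, tgp1 and seb1, and overlap them for rpb1, at means of 151 and 152 CPM.

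The list of phosphate acquisition genes, fixed before the data were examined, therefore had 3 of 3 members higher, also 3 when adjusted over the list alone. In camera, a test of a list against all other features, its adjusted p was 0.00555, against adjusted p = 0.5999 with an estimated correlation between its genes. The wider list of genes repressed by an upstream lncRNA had 5 members, with 3 higher and 0 lower, also 3 and 0 when adjusted over the list alone. Its other members were the aldehyde dehydrogenase gene atd1, with a log2 fold change of 0.43 (adjusted p = 0.135), and the kinase gene byr2, at -0.13. The camera adjusted p of this list was 0.0279, with adjusted p = 0.5999 with an estimated correlation and 0.0647 without wild-type replicate 3. SPBC8E4.02c rose from 12.3 ± 0.901 to 17.7 ± 1.70 CPM (log2 fold change 0.52, adjusted p = 0.00585). The authors' deposited comparison describes it as a Schizosaccharomyces pombe specific protein. The reference annotation used here matched it to prt2, the lncRNA gene directly upstream of pho84 on the same strand. Whether the counted feature spans that lncRNA was not checked, so its level need not be that of prt2. The lncRNAs upstream of pho1 and tgp1 were not analysed here.

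Among the regulators of phosphate and inositol pyrophosphate metabolism, 4 of 7 tested genes were higher and 1 was lower, the same counts as adjusted over the list alone. The polyphosphate synthesis gene vtc4 rose by a log2 fold change of 1.15, from 229 ± 17.3 to 508 ± 32.4 CPM. The gene of the transcription factor Pho7, an activator of pho1, had a log2 fold change of 0.48, and the kinase gene csk1 one of -0.58. The inositol pyrophosphate synthase gene asp1 was called at 0.27 (adjusted p = 0.0429), a call that was lost with library totals alone as scaling (adjusted p = 0.301) and without any one library other than wild-type replicate 3 (0.078 to 0.167). As a set this list did not pass camera (adjusted p = 0.348).

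Across the transcriptome, 3328 of 6046 tested features (55%) changed at an adjusted p under 0.05, with 1613 higher and 1715 lower in the mutant. A change of at least 2-fold was found for 352 higher and 198 lower features. The groups did not overlap for 63.9% of the tested features, where chance gives 10%. The biological coefficient of variation was 9.59%. Scaling by library totals alone moved the median log2 fold change by -0.119 and the share of calls that were higher from 48.5% to 33.4%, and it gave 305 features lower by at least 2-fold.

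The largest rise was that of snR93, a box H/ACA small nucleolar RNA, from 0.438 ± 0.193 to 31.5 ± 0.918 CPM (log2 fold change 6.13). The libraries were made from polyadenylated RNA, so this need not be a change in the total level of snR93. Antisense features followed, with log2 fold changes of 4.64 for cwf28-antisense-1 and 4.25 for ctp1-antisense-1, both also annotated as a possible alternative UTR. SPNCRNA.388 was called at 4.41 (adjusted p = 0.0116), but its mutant libraries were at 27.3, 1.71 and 1.94 CPM, so mutant replicate 1 set its size. SPNCRNA.1258 rose by 3.87, SPNCRNA.99 by 3.38, prl14 by 3.32 and SPNCRNA.1147 by 3.06. Among protein-coding genes, the uncharacterised SPBC1711.15c rose by a log2 fold change of 3.35, dad5, a subunit gene of the kinetochore DASH complex, by 3.27, and cta3, a cation-transporting ATPase gene, by 2.85.

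Of the 12 largest falls, 6 were of protein-coding genes, led by mug94 with a log2 fold change of -2.77 and ste4, an adaptor of the pheromone response, with -1.89. The shugoshin gene sgo1 was at -1.82, the CENP-C gene cnp3 at -1.80, and SPCC569.03 at -1.77. The apoptosis-inducing factor homologue aif1 was at -1.62. The remaining 6 were annotated as non-coding: ctf8-antisense-1 at -2.0, SPNCRNA.1390 at -1.93, omt3 at -1.87, SPNCRNA.1334 at -1.80, SPNCRNA.1102 at -1.78, and rrk1, the RNA of RNase P, at -1.68. As for snR93, the value of rrk1 is for polyadenylated RNA and need not reflect its total level.

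Annotated non-coding features rose more often than they fell. Of 1013 tested features with a non-coding identifier, 381 (37.6%) were higher and 146 (14.4%) lower, or 381 and 144 when adjusted over the list alone, and 201 rose and 57 fell by at least 2-fold. Antisense RNAs accounted for 271 higher and 62 lower among 616 tested, while intergenic RNAs were split into 83 higher and 73 lower among 326. Features annotated as a possible alternative UTR, a label that overlaps the antisense and intergenic ones, had 91 higher and 14 lower among 182. Protein-coding genes went the other way, with 1202 (24.3%) higher and 1562 (31.5%) lower among 4953. The median log2 fold change was 0.30 for the non-coding features and -0.046 for the coding genes. The camera adjusted p of the non-coding list was 0.000205, and adjusted p = 0.5999 with an estimated correlation. The strand option of the authors' counting was not given in the sources used here, so the split of reads between a gene and its antisense feature is not settled by them. In the counts, coding genes lying wholly under an opposite-strand feature kept a median of 31.8 CPM, where counting without strand would by default leave such reads unassigned.

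**Figure D2:**
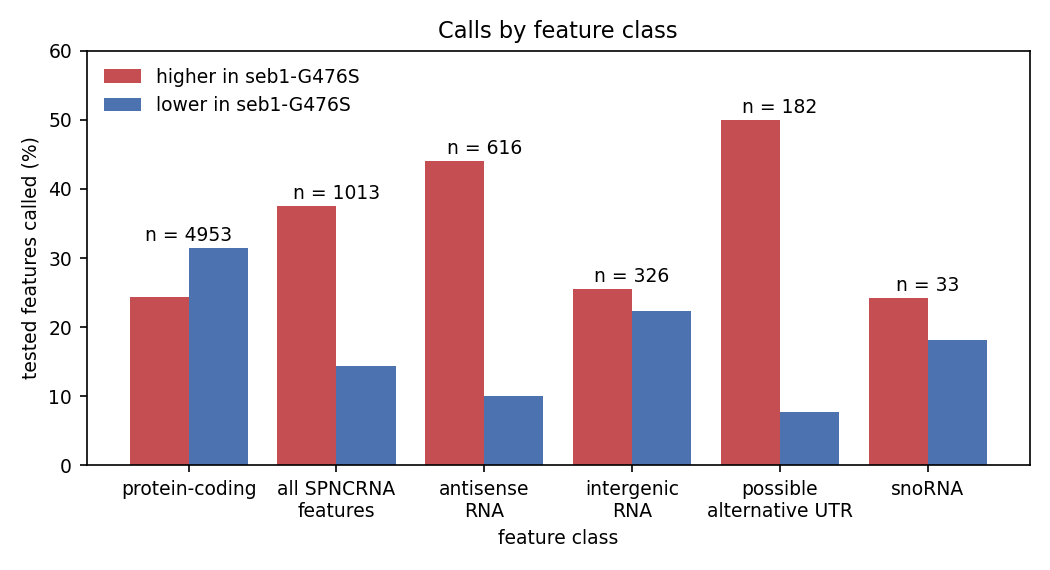
Percentage of tested features called higher (red) or lower (blue) in seb1-G476S at an adjusted p under 0.05, by feature class, with the number tested above each pair of bars. Antisense RNAs were called higher in 44% and lower in 10.1%, and protein-coding genes in 24.3% and 31.5%. The possible alternative UTR class overlaps the antisense and intergenic classes.

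Genes of nuclear RNA decay fell. Of 23 tested members, 17 were lower and 2 higher, also 17 and 2 when adjusted over the list alone. The exosome subunit gene rrp4 had a log2 fold change of -0.97, red5, of a complex that eliminates meiotic transcripts, -0.96, and the TRAMP polyadenylation complex genes air1 and cid14 -0.71 and -0.70. By camera the adjusted p was 0.00352, and adjusted p = 0.5999 with an estimated correlation. Genes for kinases and phosphatases of the polymerase C-terminal domain (CTD) and for elongation factors fell as well, with 12 lower and 2 higher among 20, also 12 and 2 when adjusted over the list alone. The CTD phosphatase gene ssu72 was at -1.04, the elongation factor gene tfs1 at -0.80, the CTD kinase gene cdk9 at -0.71, and the Paf1 complex gene cdc73 at -0.65. Here the camera adjusted p was 0.0153, and adjusted p = 0.5999 with an estimated correlation. Weakly expressed coding genes tended to be lower, with a median log2 fold change of -0.30 among the 2476 below the median CPM. Of these, 1131 were called lower and 333 higher. The same genes had a median deviation of 0.152 from the wild-type mean in wild-type replicate 3, opposite to the mutant libraries.

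Factors of cleavage, polyadenylation and termination were mixed, with 5 higher and 10 lower among 27 and a camera adjusted p of 0.348, and the same counts adjusted over the list alone. Their largest rise was that of the cleavage factor gene msi2, from 40.6 ± 6.21 to 141 ± 1.32 CPM (log2 fold change 1.79), followed by seb1. Their largest falls were ssu72 and cwf25, at -0.96, which encodes a spliceosome-associated protein. Among 11 histone genes, 2 were higher and 7 lower, also when adjusted over the list alone, with hht3 at -0.62, hht1 at -0.59 and hhf3 at -0.50 and with cnp1, the centromeric histone H3, at 0.61 (camera adjusted p = 0.105, and 0.0465 with library totals alone). For the 3 tested Tf2 retrotransposons, near-identical copies make the counts uncertain. Of these, 0 were higher and 1 was lower, likewise when adjusted over the list alone (camera adjusted p = 0.169). The lower member was Tf2-2, at -1.52, from 0.90 ± 0.261 to 0.313 ± 0.0466 CPM.

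Iron homeostasis genes rose, with 13 higher and 0 lower among 18, or 14 and 0 when adjusted over the list alone. The siderophore transporter gene str3 rose from 0.351 ± 0.0379 to 3.33 ± 1.53 CPM (log2 fold change 3.23) and the heme uptake gene shu1 from 0.31 ± 0.105 to 2.81 ± 0.754 CPM (3.16), both from levels of under 1 CPM. The iron permease gene fip1 rose by 1.07 and the iron-sulfur cluster assembly gene isu1 by 1.00. In camera this list had an adjusted p of 0.000242, and adjusted p = 0.5999 with an estimated correlation. Copper and zinc homeostasis genes had 3 higher and 3 lower among 13, also when adjusted over the list alone, with cuf1 at -0.45, loz1 at 0.45, ctr6 at -0.29 and zhf1 at 0.27. That list did not pass camera (adjusted p = 0.913, and 0.741 in the opposite direction with library totals alone).

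Stress-responsive genes rose on balance. The core environmental stress response had 16 higher and 6 lower among 36, or 16 and 7 when adjusted over the list alone, led by cta3, hri1, a kinase of the translation factor eIF2 alpha, at 1.51, and the Hsp70 gene ssa1 at 1.34, and with aif1 lower. Its camera adjusted p was 0.0279, with adjusted p = 0.5999 with an estimated correlation and 0.0695 without wild-type replicate 3. Heat-shock chaperones had 10 higher and 2 lower among 18, also when adjusted over the list alone, with ssa1, the disaggregase gene hsp104 at 0.67 and the DnaJ-domain gene psi1 at 0.61 higher, and the Hsp90 co-chaperone gene cdc37 at -0.55. The camera adjusted p of the chaperones was 0.0465, with adjusted p = 0.5999 with an estimated correlation, and it was 0.0676 without wild-type replicate 2, 0.0681 without wild-type replicate 3, 0.05004 without mutant replicate 2 and 0.0605 without mutant replicate 3.

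Glucose-repressed genes and hexose transporters had 10 higher and 2 lower among 20, also when adjusted over the list alone. The hexose transporter gene ght6 was at 1.41, from 0.566 ± 0.17 to 1.49 ± 0.233 CPM, the invertase gene inv1 at 1.22, and the gluconeogenic gene fbp1 at 0.91, while SPBC1683.11c, annotated as isocitrate lyase, was at -0.97. As a set they passed camera, with an adjusted p of 0.0157, and adjusted p = 0.5999 with an estimated correlation. Genes of amino acid transport and biosynthesis had 15 higher and 4 lower among 45, also when adjusted over the list alone, with the amino acid transporter genes meu22 at 0.99 and agp3 at 0.64, lys7 of lysine synthesis at 0.62, and gap1 at -0.37, which encodes a Ras GTPase-activating protein rather than a transporter. The camera adjusted p of 0.0465 did not hold with adjusted p = 0.712 with an estimated correlation, 0.270 with library totals alone, 0.0537 with no low-count filter, 0.0767 without wild-type replicate 2, 0.1997 without wild-type replicate 3, 0.119 without mutant replicate 1 and 0.05004 without mutant replicate 2.

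The 3 lists on sexual differentiation did not pass camera. Of 24 meiotic genes controlled by the RNA-elimination factor Mmi1, 9 were higher and 3 lower (camera adjusted p = 0.404), with num1, a dynein anchor also called mcp5, at 2.04, rec10 of meiotic recombination at 1.24 and mpf2 at -1.50. The gene mug45 was called at 1.30 (adjusted p = 0.0263) from a wild-type level of 0.746 ± 0.56 CPM, and the call was lost with library totals alone (0.0639) and without any one library other than wild-type replicates 1 and 3 (0.0569 to 0.0704). Of 26 genes of mating and nitrogen starvation, 6 were higher and 8 lower (camera adjusted p = 0.356). Among them ste4 was lower, the meiotic regulator gene mei2 was at -1.26 and inv1 was higher. The meiosis inducer gene mei3 was at 1.91, from 0.389 ± 0.188 to 1.49 ± 0.192 CPM. Of 7 tested markers listed for M cells, 3 were higher and 0 lower (camera adjusted p = 0.471). The counts adjusted over the list alone were the same in all 3 lists. The member with the largest rise, map3 at 1.04, encodes the receptor for M-factor, which is used by cells of the opposite mating type. The M-factor gene mfm1 at 0.94 and the adhesin gene mam3 at 0.18 lost their calls in several alternatives. The mating-type genes mat1-Mc and mat1-Mi and the marker gene ura4 had 0 counts in every library, where 3 counts would correspond to between 0.111 and 0.134 CPM. A count of 0 does not tell an absent transcript from one whose reads were left unassigned.

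Other lists did not pass camera. Cytosolic ribosomal protein genes had 30 higher and 20 lower among 149, or 24 and 19 when adjusted over the list alone (camera adjusted p = 0.348). The list took 8 antisense features by its name pattern. Among them rpl1801-antisense-1 was at 1.53, from 0.298 ± 0.128 to 0.856 ± 0.145 CPM. Without the antisense features the list had 27 higher and 20 lower among 141. Its direction turned with library totals alone (adjusted p = 0.700), and it passed without wild-type replicate 1 (0.0355). Among its protein-coding members the largest change was that of rpl3801, at -0.70. Oxidative phosphorylation genes had 14 higher and 7 lower among 36, or 16 and 7 when adjusted over the list alone, with qcr7 at 0.56, cox13 at -0.54, qcr6 at -0.42 and atp17 at 0.41 (camera adjusted p = 0.105, and 0.0392 without wild-type replicate 1).

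Thiamine-regulated genes had 3 higher and 0 lower among 11, also when adjusted over the list alone, namely tnr3 at 0.58, thi5 at 0.35 and thi9 at 0.27, whose own call was lost with library totals alone (adjusted p = 0.154) and in 3 of the 6 fits without 1 library (camera adjusted p = 0.322). Genes of flocculins and the cell surface had 11 higher and 6 lower among 24, also when adjusted over the list alone (camera adjusted p = 0.169). In this group the glucanosyltransferase gene gas4 was at -1.04 and gas2 at 0.83, the transcription factor gene mbx2 at 1.02 and the flocculin gene pfl7 at -0.78. Of 8 tested strain marker genes, ade6 was called at 0.22 (adjusted p = 0.018), which did not hold when adjusted over the list alone, where 0 were called. The marker gene leu1 was at -0.041 (adjusted p = 0.557), and with library totals alone the log2 fold change of leu1 was -0.16 (adjusted p = 0.00595). The strain marker list had a camera adjusted p of 0.541, and its direction turned with library totals alone (0.891).

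**Figure D3:**
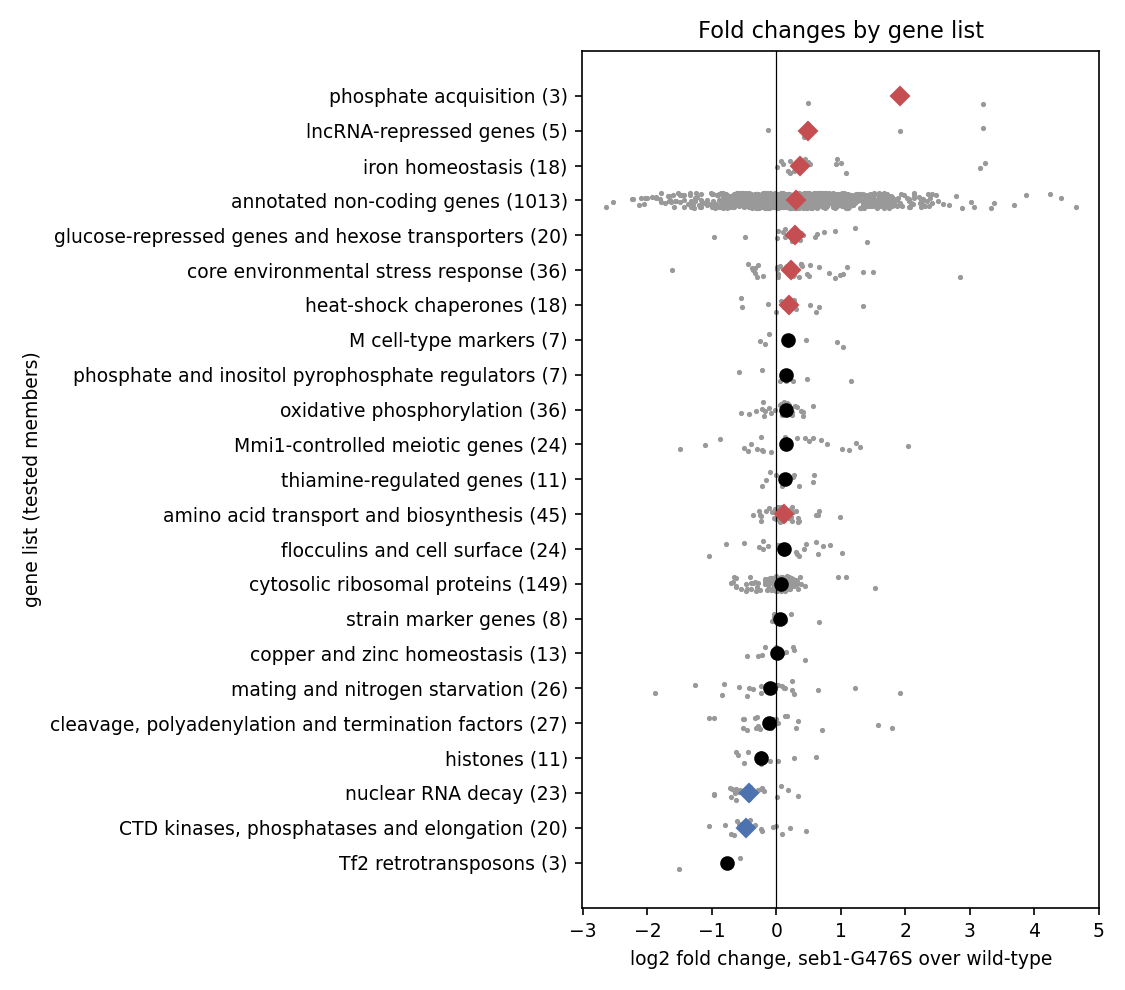
Log2 fold change of seb1-G476S over wild-type for every tested member (grey points) of the 23 gene lists, ordered by their medians. Diamonds mark the median of lists that passed camera at an adjusted p under 0.05 (red, up; blue, down) and black circles that of the others; with an estimated correlation none of the 23 lists passed (adjusted p of 0.5999 or more). The median was 1.92 for phosphate acquisition and -0.43 for nuclear RNA decay. With library totals alone as scaling, the direction of the ribosomal protein, strain marker and copper and zinc lists turned.

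Protein-coding genes with an annotated non-coding gene directly upstream on the same strand were examined as a class. This arrangement is found at pho1, pho84, tgp1, atd1 and byr2. Of 2446 such genes, 652 (26.7%) were higher and 684 (28%) lower, against 550 (21.9%) higher and 878 (35%) lower among the other 2507 coding genes. Their median log2 fold change was -0.0074, against -0.084 for the others. The difference did not pass camera (p = 0.116, and p = 0.118 with an estimated correlation). Longer coding genes had slightly higher fold changes, with a Spearman rho of 0.125 across 4953 genes, which are not independent replicates. Among the 1651 shortest genes 18.7% were higher and 38.8% lower, and among the 1651 longest 29.1% were higher and 25.2% lower.

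The fitted fold changes were also set beside the authors' deposited table. It rests on the same libraries, perhaps with others, so it is not independent of the fits here. Across 6045 features the Pearson correlation of the log2 fold changes was 1.00. The authors' deposited table called 3113 features, 1632 higher and 1481 lower, of which 2936 were called here in the same direction and 0 in the opposite one. For the phosphate genes the authors' deposited table gave log2 fold changes of 3.24 for tgp1, 1.96 for pho1 and 0.52 for pho84, and 1.61 for seb1.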

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

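Coding genes tested alone and lists set against coding genes were chosen after seeing the data; the other alternatives below were planned. Counts of calls stayed within 1.5 times of the reported ones in each alternative, except those lower by at least 2-fold, which were 305 with library totals alone, and both 2-fold counts with fewer features tested: 158 higher and 120 lower without non-coding identifiers, and 138 and 117 for coding genes alone. Leaving out 1 library kept between 75.3% and 95% of the 3328 calls. The replicate numbers were not taken to pair the samples, since deviations of same-numbered libraries correlated at 0.357, 0.0585 and 0.263, not all over 0.1. As a hint from the data, 5 of the 6 libraries correlated best with their own number in the other group, and mutant replicate 2 did so with wild-type replicate 3. The fit with a replicate block called 3906 features and kept 3318 of the calls.

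With library totals alone the direction turned for the copper and zinc (0.741), strain marker (0.891) and ribosomal (0.700) lists, the amino acid list lost its call (0.270), and the histone list gained one (0.0465). With no low-count filter the amino acid list was at 0.0537. With an estimated correlation the adjusted p of every list called was 0.5999, or 0.712 for amino acids, in a test that differs both in the correlation and in resting on the 4 residual degrees of freedom, which were not taken apart. Under fry, calls were gained by the phosphate regulators (0.0416), thiamine (0.0297), flocculin (0.00842), Tf2 (0.00552) and histone (0.00552) lists, and amino acids lost theirs (0.0861). Against coding genes, oxidative phosphorylation was at 0.0334. The cause of these changes in list calls was not tested.

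Leaving out 1 library changed some list calls, for which the lowest and highest adjusted p are given. The ranges were 0.0355 to 0.937 for ribosomal proteins, 0.0392 to 0.272 for oxidative phosphorylation, 0.0143 to 0.0647 for lncRNA-repressed genes, 0.00639 to 0.0695 for the stress response, 0.0186 to 0.0681 for chaperones and 0.00639 to 0.1997 for amino acids. In these, the first 2 gained a call without wild-type replicate 1, and lncRNA-repressed genes and the stress response lost theirs without wild-type replicate 3. The correlation with the deposited fold changes ranged from 0.981, without wild-type replicate 3, to 0.996. Of 99 named genes, 3 changed sign in an alternative, and none of the 3 was called as reported or in the fit where its sign changed, though leu1 was called lower with library totals alone (log2 fold change of leu1 -0.16, adjusted p = 0.00595): without 1 library the log2 fold change of rpb1 ranged from -0.0676 to 0.0487, the log2 fold change of leu1 from -0.0711 to 0.0012 and the log2 fold change of sxa2 from -0.226 to 0.118, and with the stricter filter rpb1 was at 0.00077. DESeq2 left 1 adjusted p undefined. In the simulation, where far fewer features changed than were called in the data, a 1.5-fold change was recovered in 70.1% of 67 features.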

Other observations

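The features in these opening paragraphs were chosen after their values were seen, from 6046 tested with 1613 higher and 1715 lower, and were not tested as groups. A predicted plasma membrane phosphate transporter gene, SPAC23D3.12, rose from 300.004 ± 14.3 to 1152 ± 53.8 CPM (log2 fold change 1.94, edgeR adjusted p = 4.94e-08). The polyphosphate synthesis gene vtc2 rose by a log2 fold change of 1.01 (adjusted p = 1.8e-06), and SPAC1039.02, a predicted extracellular 5'-nucleotidase, by 1.43 (adjusted p = 0.000407). Beside pho84, ecl3, a gene linked to chronological lifespan, rose by 1.91 from 2.96 ± 0.413 CPM. SPNCRNA.1343, near tgp1, fell by 1.19 on the log2 scale.

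The log2 fold change was 2.31 for urg1, a predicted GTP cyclohydrolase gene, from 173 ± 46.7 to 854 ± 18 CPM, 2.08 for urg2 and 1.11 for uck2, both annotated as uracil phosphoribosyltransferases, and 0.93 for urg3, each higher in 3 of 3 mutant libraries. The mitochondrial guanine nucleotide transporter gene ggc1 rose by 2.29, from 25.6 ± 1.40 to 126 ± 7.02 CPM, while its neighbour mpf2 was at -1.50. Of 17 tested 5S rRNA features, 12 were higher and 0 lower, at levels of a few CPM or less. Their near-identical copies make single features uncertain. The libraries were of polyadenylated RNA, so these values need not reflect total 5S rRNA.

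The tests of explanations, of sense partners and of splits below were chosen after the results were seen, and the camera tests before. Of 1013 non-coding features 381 were higher, 146 lower and 486 not called (camera adjusted p = 0.000205, and adjusted p = 0.5999 with an estimated correlation). For those that rose, the values argue against constant strand leakage and weak expression as the whole cause, within the limits given below. If reads leaked from the sense strand at a constant rate, the sense partners would rise too, but the partners of the 202 antisense features called higher whose name gives a tested sense gene had a median log2 fold change of -0.257 (95% interval -0.393 to -0.195). One changed rate of leakage for all pairs, set at the median gain per sense CPM, gave a median of 11% of the gain per feature (5.24 to 17.6). These features were picked for their rise, which lowers that share, so the test cannot decide how much such leakage contributed. A correlation tried before this test, which shares the wild-type antisense level with the fold change, was 0.186 (0.0939 to 0.272). It lay in the direction of such leakage. Weak expression alone would raise coding genes of matched CPM. Of the 1013 non-coding features, 623 had a match within 0.1 log2 units. The matched coding genes had a median of -0.295, against 0.309 for those 623 features. The unmatched features were not covered. A candidate explanation that stays open is extension of the coding transcript upstream. For 200 features the nearest annotated gene upstream on the same strand was coding and overlapped the feature or ended within 500 bp. These had a median of 0.55, against 0.25 for the other 813, a difference of 0.298 (0.092 to 0.411, two-sided permutation p = 0.00012). The other 813 may include features with a coding gene as close but a non-coding gene nearer.

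For the 113 antisense features raised at least 2-fold whose name gives a tested sense gene, the sense partners had a median log2 fold change of -0.32, against -0.10 for the 333 other pairs (two-sided permutation p = 0.0024). Examples are cwf28, at -1.39 where cwf28-antisense-1 rose by 4.64, and ctp1, at -0.80 where ctp1-antisense-1 rose by 4.25. Both antisense features are also annotated as a possible alternative UTR. The nearest gene upstream of snR93 on its strand, rpl29, was at -0.28. The pairs were not matched on the level of the sense gene. Coding genes below the median CPM had a median of -0.299 in general, and the others 0.0828. The comparison of sense partners therefore cannot separate the antisense rise from expression level. Features are not independent replicates, and no cause was tested.

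The seb1 mRNA was 2.97-fold higher. An extra copy of the region would raise the 5 tested features on each side of seb1, but their median log2 fold change was -0.0569 (-0.606 to 0.236). Scaling is argued against by the lowest value of seb1 over 12 alternatives, 1.45. A copy of seb1 alone, a more stable transcript or altered transcription of seb1 by its own product may each remain open and were not tested.

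Coding genes below the median of mean CPM tended to fall, with 333 higher and 1131 lower among 2476, while the 2477 others had 869 higher and 431 lower. Wild-type replicate 3 deviated the opposite way to the mutant. Without it the median log2 difference of the weaker genes was -0.209, against -0.275 with it, so in these libraries the fall did not rest on it alone. The interval of -0.227 to -0.192 is over genes and does not measure the spread between cultures. Wild-type replicates 1, 2 and 3 had median deviations of -0.117, -0.031 and 0.152 from the wild-type mean. Variation between cultures stays open, since wild-type replicate 3 minus 2 and the mutant mean minus wild-type replicate 1, which share no library, correlated across 4953 genes at a Spearman rho of -0.238. The axis along which wild-type cultures differ may therefore contribute to many small falls, and whether it does for the RNA decay and CTD genes was not tested.

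Of the 10 splits of the 6 libraries into 3 and 3, the real one included, only the real one reached 3328 calls (highest other 0). It was also the only one with 550 calls of at least 2-fold (highest other 0). Such a design cannot give a share under 0.05. Every other split put both strains in each group, where a strain difference widens the spread, so the 0 calls there say little about chance. For gene lists past the threshold, 3 splits, the real one among them, reached the real number of 10, and the highest other had 13. For the upstream neighbours, only the real split reached its value of 0.934 for minus log10 p, with 0.797 the highest other.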
